A study of Mus musculus with 18 samples.

How the data were processed

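Messenger RNA of MII oocytes (3 WT and 3 KO libraries) and small RNA of sperm (2 WT and 2 KO) were analysed from the deposited processed files. The blastocyst methylation samples were not analysed here. Groups and replicate numbers came from the sample titles. The labels do not say that replicates came from separate animals or how many oocytes went into each library, so p-values measure the spread between these samples, which may be technical. The only library protocol in the labels describes blastocysts (a single-cell full-length amplification kit, a transposase library kit and a NovaSeq X Plus), and it is repeated for the oocyte and sperm samples.

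The oocyte files held, per the file headers, RSEM expected counts, TPM and FPKM for 55471 Ensembl gene IDs. Trim Galore 0.4.5, STAR 2.6.1c, RSEM 1.3.1 and DESeq2 1.42.1 with the mm10/GRCm38 build were named in the submitters' processing notes, without their roles. The annotation release and strand setting were not given in the sources used here, so reads of antisense or overlapping genes cannot be separated. RSEM shares reads that map to several genes among them, which leaves close relatives such as the Nlrp4 genes uncertain. The FPKM values, per the file headers scaled to length and library by the authors, were not used. The TPM values deposited by the authors entered 1 pair of alternatives and the correlations. A symbol was found for 55144 of the IDs, and coordinates came from a RefSeq table of GRCm38.p6.

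The sperm files held 1 line per distinct sequence of 20 to 45 nucleotides with its whole read count, as deposited, a genome match and an annotation string. The annotation tool was not given in the sources used here. Reads were summed per annotation string as each file gave it, leaving out sequences without annotation (8.71% to 20.4% of reads). Of 207217 distinct sequences, 1100 had different strings in different files, and 39 still did after the names in each string were sorted. Classes were read from the first name of the string. A microRNA needed a specific mouse microRNA name and an rRNA a named subunit. Strings that began with the bare word miRNA or rRNA were counted among other labels.

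Expected counts were rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, Benjamini-Hochberg adjustment, threshold 0.05), with genotype as the only term. The same test was used for sperm. The standard error of a log2 fold change was its size divided by the root of the F statistic. CPM values used TMM-scaled library sizes. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01) on log CPM with a prior count of 2, beside an estimated correlation and fry. The 19 gene lists and 4 small RNA lists were fixed before the data were examined, as were the tests and the alternatives listed below unless said otherwise. The lists covered iron-sulfur assembly, iron handling, other iron-sulfur proteins, the nuclear and the mitochondrially encoded respiratory chain, the tricarboxylic acid cycle, DNA methylation, JmjC demethylases, oocyte genes, meiosis, messenger RNA decay, antioxidant genes, stress responses, small RNA pathways, cytosolic and mitochondrial ribosomal proteins, 2-cell transcripts, granulosa cells and blood. The small RNA lists covered spermatogenic, epididymal and other-cell microRNAs and tRNA parents. A microRNA family name had to end where the family number ends, so that mir-1 did not take in mir-10b.

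Genes were named by a rule fixed before the data were examined. It took Isca2, the 8 genes with the largest and the 8 with the smallest log2 fold change among called genes with a mean log2 CPM of at least 2, separated groups and an ordinary symbol, the 2 members of each list with the smallest p (3 for DNA methylation and iron-sulfur assembly), and Tet1, Tet2, Tet3, Dnmt1 and Dnmt3a. For sperm it took the 4 annotations with the smallest p in each direction when none was called, the 5 most abundant microRNAs, the 3 most abundant tRNA annotations and 2 members of each list. A list member that this rule picked is not reported here. In the 6 oocyte libraries 0 genes met the part on called genes. That part was then applied to the fit without WT replicate 3, a use chosen after the data were seen. The genes named as immune markers of WT replicate 3, the library-weighted fit, the other tools on 5 libraries, the thinned counts, the matched random lists and the class of all genes with a count from which they were drawn were also chosen after the data were seen. So were 2 sperm alternatives, sorted annotation names and library sizes without rRNA reads. Gja1, Hsd3b1, Fst and Igf1 are not in the fixed granulosa list and were also named after the data were seen.

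The alternatives, most of which changed 1 choice, were: RLE factors or library totals for TMM, DESeq2 1.42.0 or limma-voom for edgeR, other count filters, the replicate number as a block, log2 of TPM plus 1 or 0.1, a 2-fold minimum, no mitochondrially encoded genes, sequences or first names in place of annotations, microRNAs alone, and each library left out in turn. DESeq2 changed the tool, the size factors and the gene filter together, with 16188 oocyte genes and 321 sperm annotations tested. The settings without WT replicate 3 joined that change to another. Class shares carried Wilson 95% intervals and an exact two-sided permutation test over the 6 ways of choosing 2 libraries of 4. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

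The tests were tested on simulated data with known changes. In 13680 simulated genes in 6 oocyte libraries, 19% of 2-fold and 74% of 4-fold changes were recovered, with 14 false among 107 calls. In 14122 genes in 5 libraries without WT replicate 3, 63% and 94% were recovered, with 18 false among 175 calls. The oocyte changes were placed only in genes with a mean above 5 CPM, so these rates do not cover genes of lower expression. All simulated libraries shared 1 mean profile apart from the changes, so none stood apart as WT replicate 3 did. In 122 sperm annotations, of which 24 were changed, 0%, 0% and 75% of 2-fold, 4-fold and 16-fold changes were recovered, with 1 false among 7 calls. In 2527 sperm sequences the values were 0%, 7.58% and 60.6%, with 3 false among 48 calls. The 16-fold size was added after 2-fold and 4-fold changes were seen to be missed in sperm.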

Results

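The series is titled for the part that iron and the interaction of ISCA2 with the TET enzymes play around implantation. Isca2 encodes a mitochondrial protein of iron-sulfur cluster assembly, and the TET enzymes are iron-dependent dioxygenases that oxidise 5-methylcytosine in DNA. The 18 mouse samples fell into 7 groups by cell type and Isca2 genotype. Messenger RNA was profiled in oocytes arrested at metaphase of the second meiotic division (MII oocytes), with 3 wild-type (WT) libraries and 3 libraries labelled Isca2 knockout (KO). Small RNA was profiled in sperm, with 2 WT and 2 KO libraries. The embryonic day 4.5 blastocyst samples for enzymatic methylation sequencing (3 WT, 2 KO and 3 carrying the homozygous Isca2 variant G77S) were not analysed here. The oocyte libraries held between 17792157 and 30240350 expected counts. The sperm libraries held 205993 and 703036 reads in WT and 703133 and 746812 reads in KO.

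Isca2 RNA was not lower in the oocyte libraries labelled KO than in the WT libraries. Isca2 (ENSMUSG00000021241, chromosome 12, 84773230 to 84775089, GRCm38.p6) had 14, 11 and 152 expected counts in WT replicates 1, 2 and 3. It had 53, 56 and 120 in the KO replicates. The deposited TPM values were 2.35, 2.17 and 15.41 in WT and 5.66, 7.40 and 8.70 in the libraries labelled KO. The log2 fold change of KO over WT was 0.59 (SE 0.89, adjusted p = 0.907, edgeR), and without WT replicate 3 it was 2.48 (SE 0.55, adjusted p = 0.0969). DESeq2 without that library gave 2.49 with an adjusted p of 0.0109. The labels do not say which part of the gene was changed, and a count over the whole gene may not see a small deletion. Every oocyte direction below is therefore drawn between libraries as they were labelled.

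Gm15446 and Gm47180 were far lower in the oocyte libraries labelled KO. Gm15446, a long non-coding RNA gene on chromosome 5 (109933563 to 109941710, GRCm38.p6), fell from 204 ± 39.8 CPM (SD, n = 3) in WT to 2.37 ± 0.65 CPM (n = 3), which is 86.7-fold lower (log2 fold change -6.44, SE 0.29, adjusted p = 0.000838). Gm47180 fell from 116 ± 14.5 to 3.22 ± 0.99 CPM, which is 36.3-fold lower (log2 fold change -5.18, SE 0.27, adjusted p = 0.00121). All 3 libraries labelled KO lay below all 3 WT libraries for both genes, and both were named after their values were seen. Of 13680 genes tested with edgeR, these 2 were called lower and 0 were called higher. At an unadjusted p under 0.05, 396 genes were higher and 451 lower. DESeq2 called 96 higher and 25 lower, and limma-voom called 0 and 2. Leaving out WT replicate 3 raised the edgeR calls to 81 higher and 11 lower, and leaving out KO replicate 1 left 1 gene lower.

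No gene of DNA methylation or of the TET family passed the test after adjustment in the 6 oocyte libraries. Tet3, the main TET enzyme of the oocyte, had 514 ± 92.9 CPM in WT and 469 ± 33.5 CPM in the libraries labelled KO (log2 fold change -0.13, SE 0.16). WT replicate 3 had 407 CPM of Tet3, below the 567 and 569 CPM of WT replicates 1 and 2. Without it the Tet3 log2 fold change was -0.28 (SE 0.10, adjusted p = 0.296, edgeR). Dnmt1, the maintenance methyltransferase, had 716 ± 36.4 and 685 ± 41.0 CPM (-0.06, SE 0.11), and Dnmt3a had 70.0 ± 7.41 and 66.3 ± 11.1 CPM (-0.08, SE 0.16). Tet1 had 8.64 ± 2.56 and 11.6 ± 1.77 CPM (0.43, SE 0.30). Tet2 had 6.22 ± 1.94 and 2.15 ± 1.48 CPM (-1.53, SE 0.59, adjusted p = 0.766), with every library labelled KO below every WT library, while Mbd1 and Dnmt3l gave log2 fold changes of -0.65 (SE 0.36) and -0.35 (SE 0.21). None of the 19 members of this list was called, over all genes or adjusted over the list alone. The camera test gave an adjusted p of 0.500 and a median log2 fold change of -0.08. Of the iron-dependent JmjC histone demethylases, 0 of 18 tested members were called (camera adjusted p = 0.573), with Kdm5a at 0.71 (SE 0.22) and Phf2 at -0.63 (SE 0.37).

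None of the tested genes of iron and iron-sulfur metabolism was called in the 6 oocyte libraries. In the iron-sulfur assembly list 0 of 24 tested members were called (median log2 fold change 0.04, camera adjusted p = 0.573). Isca1, the partner of ISCA2, had 79.8 ± 30.7 CPM in WT and 49.4 ± 2.68 CPM in the libraries labelled KO (log2 fold change -0.69, SE 0.26, adjusted p = 0.766). Without WT replicate 3 the Isca1 log2 fold change was -0.34 (SE 0.14, adjusted p = 0.391, edgeR). The ferredoxin gene Fdx1 had a log2 fold change of 0.42 (SE 0.18), and Narfl, the gene listed as Ciao3, had -2.94 (SE 1.11), and -1.56 (SE 1.13) without WT replicate 3. Among 15 genes of iron uptake, storage and export, the ferritin heavy chain gene Fth1 had 1674 CPM in WT replicate 3 and between 18.2 and 75.6 CPM in the other 5 libraries, and Cisd1 had a log2 fold change of -0.79 (SE 0.35). The camera adjusted p of that list was 0.991. The list of 21 other iron-sulfur proteins, with Ddx11 at -0.47 (SE 0.25), had a camera adjusted p of 0.573. The tricarboxylic acid cycle and lipoylation list of 20 genes, with Suclg2 at 0.33 (SE 0.12) and Dlst at -0.88 (SE 0.44), had 0.584.

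Mitochondrially encoded messenger RNAs and granulosa or cumulus markers were the leading lists on the higher side in the libraries labelled KO. Of the 13 mitochondrial messenger RNAs, 12 had a positive log2 fold change (median 0.40), led by mt-Co3, a subunit of cytochrome c oxidase, at 556 ± 21.8 CPM in WT and 838 ± 135 CPM (log2 fold change 0.59, SE 0.14, adjusted p = 0.612). The exception was the complex I subunit gene mt-Nd3, at 28.8 ± 8.36 and 7.36 ± 1.78 CPM (-1.97, SE 0.31, adjusted p = 0.220). Adjusted over the list alone, 1 member was higher and 1 lower. The camera adjusted p was 0.00193 for this list, and 0.807 with an estimated correlation. Of 12 tested granulosa and cumulus markers, which belong to the somatic cells around the oocyte, 9 were higher (median 0.83, camera adjusted p = 0.00193, adjusted p = 0.807 with an estimated correlation). Adjusted over the list alone 2 markers were higher. Hsd17b1, a steroid dehydrogenase gene, had 0.53 ± 0.55 CPM in WT and 11.6 ± 9.03 CPM, and the inhibin subunit gene Inhbb had 0.01 ± 0.03 and 6.69 ± 5.67 CPM.

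Of the 77 mitochondrial ribosomal protein genes, 47 had a positive log2 fold change (median 0.07, camera adjusted p = 0.0445, adjusted p = 0.807 with an estimated correlation), with Mrps36 at 0.40 (SE 0.13) and Mrpl23 at 0.68 (SE 0.26). No member was called over all genes. The fry test, which asks whether a list differs from no change while camera compares it with the other genes, gave the mitochondrial, granulosa and mitoribosome lists adjusted p of 0.649, 0.488 and 0.649. WT replicate 3 moved with the mitochondrial list: its median there was 0.60 times that of the other WT libraries. Leaving that library out took the mitochondrial list to a camera adjusted p of 0.160, while limma-voom without it (0.00219) and the fit with library weights (0.000264) still called the list. Leaving out WT replicate 2 ended the granulosa call, and of the 6 fits that left out 1 library the mitoribosome list was called only in those without WT replicate 3 or KO replicate 1. The mitoribosome call was also lost with library totals (adjusted p = 0.0681), limma-voom (0.0808), log2 of TPM plus 1 (0.0740), the filter of 1 CPM in 3 libraries (0.0667) and without mitochondrially encoded genes (0.0612).

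The other lists did not pass the camera test in the 6 libraries with edgeR filtering and scaling. With library weights, which give WT replicate 3 the least weight, the oocyte list passed on the lower side (adjusted p = 0.00954), and the respiratory chain and cytosolic ribosomal lists on the higher side (0.00822 and 4.0e-14). The weights of WT replicates 1, 2 and 3 were 2.685, 0.835 and 0.223, so WT replicate 1 counted most. In the edgeR fit without WT replicate 3 the oocyte list did not pass (camera adjusted p = 0.155). Without a count filter the stress-response list passed on the higher side (0.0473). These calls used the preset correlation. In the main fit with an estimated correlation, the oocyte and stress-response lists had a camera adjusted p of 0.807. The respiratory chain and cytosolic ribosomal lists had 0.974 there. The maternal-effect subunit gene Ooep had 414 ± 71.6 CPM in WT and 214 ± 75.9 CPM in the libraries labelled KO (log2 fold change -0.95, SE 0.27, adjusted p = 0.766). The receptor gene Kit had 197 ± 3.43 and 151 ± 17.9 CPM (-0.38, SE 0.12), and the list of 29 oocyte genes had a camera adjusted p of 0.172. Asparagine synthetase (Asns), a target of the integrated stress response, had 7.34 ± 0.79 and 19.0 ± 2.81 CPM (1.37, SE 0.22, adjusted p = 0.233), Phgdh had 1.3 (SE 0.39), and their list had 0.172, with 1 member higher adjusted over the list alone. Mgst1 (2.88, SE 0.88, and 3.58 without WT replicate 3) and Prdx1 (0.32, SE 0.11) stood in the antioxidant list (camera adjusted p = 0.972). Atp5g3 (1.16, SE 0.27) and Ndufs4 (0.46, SE 0.17) stood in the nuclear respiratory chain list (0.573), and Rpl17 (-0.77, SE 0.29) and Rps27l (0.39, SE 0.20) among cytosolic ribosomal proteins (0.172). Aurkb (-1.14, SE 0.44) and Cks2 (0.32, SE 0.15) stood in the meiotic list (0.991), and Tut4 (2.32, SE 0.83, and 3.07 without WT replicate 3) and Tut7 (-0.33, SE 0.12) in the messenger RNA decay list (0.807).

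In the small RNA pathway list, Ago2 had a log2 fold change of -0.82 (SE 0.33) and Tdrd1 -0.32 (SE 0.14), and the camera adjusted p was 0.683. In the 2-cell stage list, Zscan4c had -1.68 (SE 0.78) and Tcstv1 0.19 (SE 0.11), with 0.683. No member of these lists was called over all genes. The medians of the iron uptake, respiratory chain, antioxidant and cytosolic ribosomal lists were negative (-0.17, -0.07, -0.23 and -0.31), as were their means (-0.34, -0.19, -0.29 and -0.32), while camera placed each of them on the higher side. The assembly and tricarboxylic acid lists had means of -0.06 and -0.002 against positive medians. Blood and immune markers had 3 tested members, too few for the test, with C1qb at -1.28 (SE 0.57, and -0.40 without WT replicate 3) and Ms4a1 at 0.12 (SE 0.11).

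**Figure D1:**
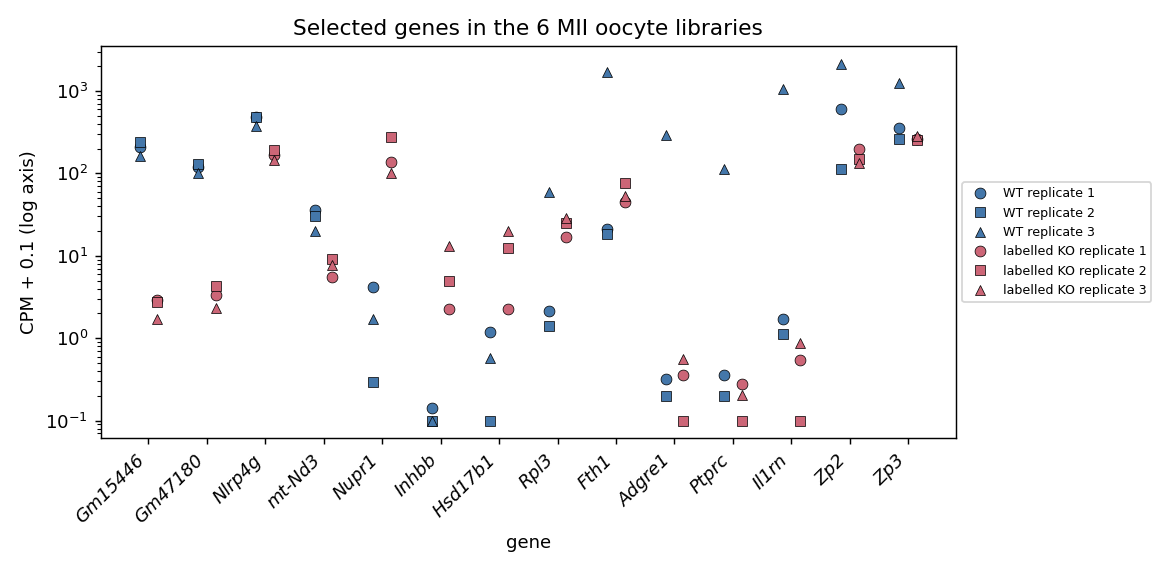
CPM plus 0.1, on a log axis, of selected genes in the 6 MII oocyte libraries. Each point is 1 library, with WT in blue and libraries labelled KO in red, and the shape gives the replicate number. Gm15446 and Gm47180 separate the groups, while WT replicate 3 stands apart for Fth1, Adgre1, Ptprc and Il1rn.

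WT replicate 3 held abundant RNA of macrophage and immune genes that were near 0 in the other 5 oocyte libraries. Adgre1, which encodes the macrophage antigen F4/80, had 289 CPM there and at most 0.46 CPM elsewhere, and the leukocyte gene Ptprc had 112 CPM and at most 0.26 CPM. The interleukin gene Il1b had 432 CPM and its antagonist Il1rn 1051 CPM, with at most 0.83 and 1.62 CPM elsewhere. Of 17 blood and immune markers with a count, 8 were over 2-fold higher in this library than in the mean of WT replicates 1 and 2, and the list median lay at percentile 100 of 10000 matched random lists. The cytosolic ribosomal protein genes had a median ratio of 4.82, with 64 of 82 over 2-fold. The oocyte genes Zp2 and Zp3, which encode zona pellucida proteins, were 5.98-fold and 4.05-fold higher there as well. Zp2 also differed between WT replicates 1 and 2 (602 and 112 CPM), and Zp3 less so (352 and 265 CPM). In all, 897 tested genes were over 4-fold higher and 10 over 4-fold lower in this library. Its Pearson correlation with the other libraries across 12208 genes lay between 0.863 and 0.883, whereas the other pairs lay between 0.956 and 0.976. Gm15446, Gm47180 and Nlrp4g had 164, 100 and 376 CPM in it, levels near those of the other WT libraries.

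Without WT replicate 3, Nupr1, Gstm1, Gstm2, Hpgd and Bex4 were among the genes that rose in the libraries labelled KO. Nupr1, a stress-induced nuclear protein gene, rose from 2.16 ± 2.77 CPM (n = 2) to 172 ± 91.0 CPM (n = 3; log2 fold change 6.27, SE 0.78, adjusted p = 0.0164, edgeR). The glutathione transferase gene Gstm1 had no count in WT replicates 1 and 2 and 10.9 ± 6.34 CPM in the libraries labelled KO, at least 78.3-fold higher against a floor of 3 counts per library. In WT replicate 3 Gstm1 had 2.345 CPM, near the 3.768 CPM of KO replicate 1. With all 6 libraries it was 13.4-fold higher (adjusted p = 0.766, edgeR). Gstm2 rose from 0.20 ± 0.15 to 7.09 ± 4.43 CPM, the prostaglandin dehydrogenase gene Hpgd from 0.46 ± 0.03 to 12.2 ± 7.63 CPM, and Bex4 from 1.93 ± 1.98 to 42.4 ± 21.5 CPM. Asns rose 2.74-fold (log2 fold change 1.45, SE 0.24, adjusted p = 0.0317). The granulosa marker Inhbb and the unfolded protein response factor Xbp1 each had 1 count over both WT libraries, and averaged 6.69 ± 5.67 and 7.07 ± 3.93 CPM in the libraries labelled KO. The other tested members of the fixed granulosa and cumulus list were not called and differed among themselves. Outside that list, Igf1 was called (log2 fold change 3.47, adjusted p = 0.0255, edgeR). Gja1, which is outside the fixed list, had 37.7, 112 and 125 CPM against 9.86 and 0.39 CPM in WT replicates 1 and 2. Inha had 0.22, 4.37 and 36.5 CPM against 5.70 and 0.15 CPM, and Cyp19a1 had 60.3, 58.4 and 52.0 CPM against 63.7 and 64.7 CPM. In WT replicate 3 Xbp1 had 26.3 CPM and Skil, a regulator of TGF-beta signalling, 73.3 CPM. Both lay above every library labelled KO, in which Skil had 16.6 ± 5.25 CPM against 0.69 ± 0.57 CPM in WT replicates 1 and 2.

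Nlrp4g, an oocyte gene of the NLR family on chromosome 9 (124348831 to 124356974, GRCm38.p6), fell from 481 ± 4 to 167 ± 22.9 CPM without WT replicate 3 (log2 fold change -1.53, SE 0.12, adjusted p = 0.00178). It had an adjusted p of 0.102 in all 6 libraries, and reads shared with its close relatives leave its level uncertain. The mitochondrial gene mt-Nd3 fell from 33.3 ± 4.20 to 7.36 ± 1.78 CPM (-2.18, SE 0.24, adjusted p = 0.0137). The histone gene Hist1h2bc fell from 102 ± 1.12 to 58.3 ± 5.05 CPM (-0.81, SE 0.12, adjusted p = 0.0260) and the poly(A) polymerase gene Papolg from 109 ± 9.92 to 64.2 ± 6.65 CPM (-0.76, SE 0.13, adjusted p = 0.0446). Papolg had 67.8 CPM in WT replicate 3, inside the range of the libraries labelled KO (56.5 to 68.1 CPM). With all 6 libraries its adjusted p was 0.766 (edgeR). Of 14122 genes tested, 81 were higher and 11 lower, and both genes called in 6 libraries were among them. DESeq2 called 415 higher and 71 lower in these 5 libraries, sharing 91 of the 92 edgeR calls, and limma-voom called 5 and 6. For 34 of the 81 higher genes, WT replicate 3 lay above every library labelled KO. In CPM it lay nearer the mean of the other WT libraries than the KO mean for 40 of the 81 higher and 6 of the 11 lower genes.

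Cytosolic ribosomal protein genes passed camera on the higher side once WT replicate 3 was left out, though not with an estimated correlation. Of 80 tested, 12 rose, among them Rpl3, Rps9 and Rps18, and none fell (median log2 fold change 0.91, camera adjusted p = 3.3e-22, adjusted p = 0.531 with an estimated correlation). Adjusted over the list alone 49 were higher and 1 lower. Rpl3 had 59.0 CPM in WT replicate 3, above the 16.7 to 28.9 CPM of the libraries labelled KO. The list median with all 6 libraries was -0.31. Of 75 nuclear respiratory chain genes, Ndufa9 and Uqcrc1 rose and 73 were not called (12 higher adjusted over the list alone, median 0.28, camera adjusted p = 5.0e-06, adjusted p = 0.531 with an estimated correlation). Gpx4, the lipid hydroperoxidase that limits ferroptosis, rose alone among 25 antioxidant genes (3 higher adjusted over the list alone, camera adjusted p = 0.0226), and Asns alone among 18 stress-response genes (4 higher adjusted over the list alone, camera adjusted p = 0.0432). With an estimated correlation both lists had an adjusted p of 0.531, and the stress-response call was also lost with library totals (0.0509) and limma-voom (0.0830). Gpx4 had 81.3 CPM in WT replicate 3, above the 14.2 to 16.7 CPM of the libraries labelled KO. The mitoribosome and granulosa lists had 0.0162 and 0.0226, with 0 of 77 and 1 of 12 members called, and each an adjusted p of 0.531 with an estimated correlation. In the iron list, Fth1 rose from 19.6 ± 1.95 to 57.6 ± 16.1 CPM (log2 fold change 1.56, SE 0.23, adjusted p = 0.0255), a call lost in limma-voom (adjusted p = 0.0791). The iron exporter gene Slc40a1 also rose, though WT replicate 3, at 6.66 CPM, lay above every library labelled KO (1.90 to 4.55 CPM). That list had a camera adjusted p of 0.160, and 0 of 25 assembly and 0 of 19 DNA methylation genes were called. Adjusted over the list alone, 3 iron genes were higher, and 1 gene each in the DNA methylation, JmjC, decay and mitoribosome lists.

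**Figure D2:**
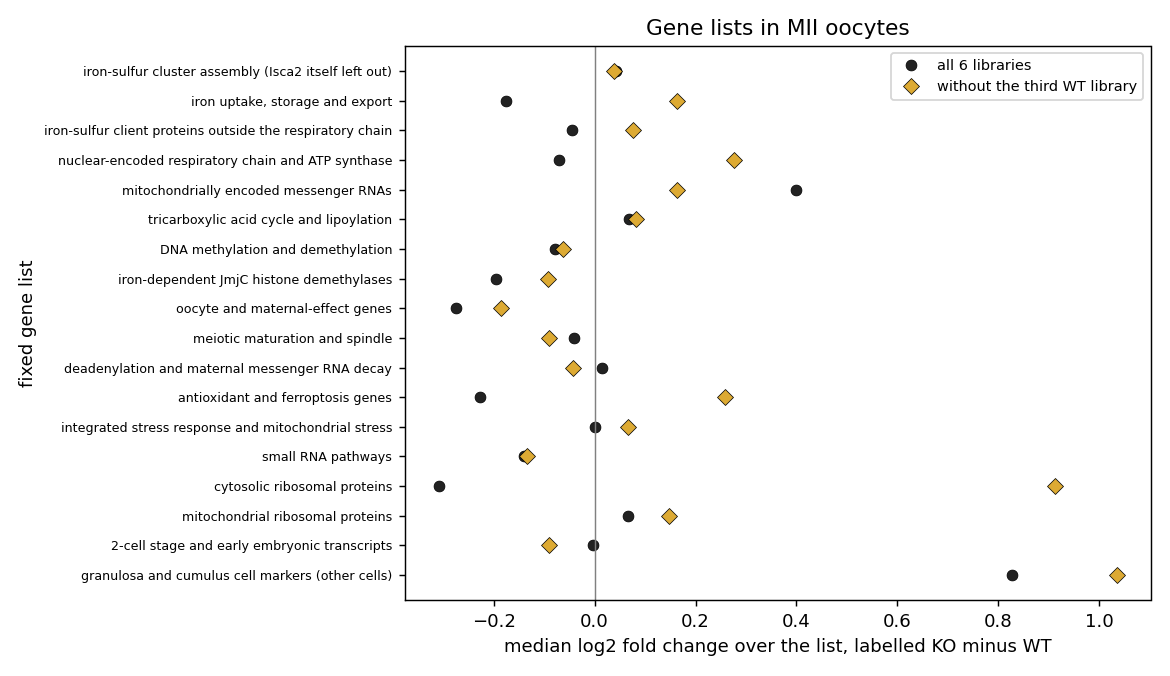
Median log2 fold change of each fixed gene list with at least 5 tested members, libraries labelled KO minus WT, in MII oocytes. Black circles use all 6 libraries and yellow diamonds leave out WT replicate 3, and the cytosolic ribosomal list lies at -0.31 with 6 libraries and at 0.91 with 5.

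Sperm of both genotypes held mostly fragments of ribosomal and transfer RNA, and the shares of the classes varied widely within WT. Nuclear ribosomal RNA made up 32.8% and 66.0% of the reads of the WT libraries, and 28.1% and 29.1% of those of the KO libraries. The means were 49.4 ± 23.5% (SD, n = 2) and 28.6 ± 0.70% (n = 2; exact permutation p = 0.333, two-sided). Nuclear tRNA fragments made up 9.81 ± 1% in WT and 16.9 ± 3.55% in KO, and piRNA annotations 2.16 ± 0.70% and 4.29 ± 0.37%, with every KO library above every WT library (exact permutation p = 0.333 for each). This p is the smallest that 2 libraries against 2 can give. As shares of distinct sequences, nuclear tRNA was lower in KO (1.37% in WT and 0.83% in KO) and piRNA differed by 0.12 percentage points. Mitochondrial tRNA fragments made up 12.9 ± 10.5% and 16.6 ± 4.20% (exact permutation p = 1), and the difference changed sign without WT replicate 2. Specifically named microRNAs made up 0.14 ± 0.09% and 0.23 ± 0.14% (exact permutation p = 0.667). In WT replicate 2, a single sequence held 34.2% of all reads.

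**Figure D3:**
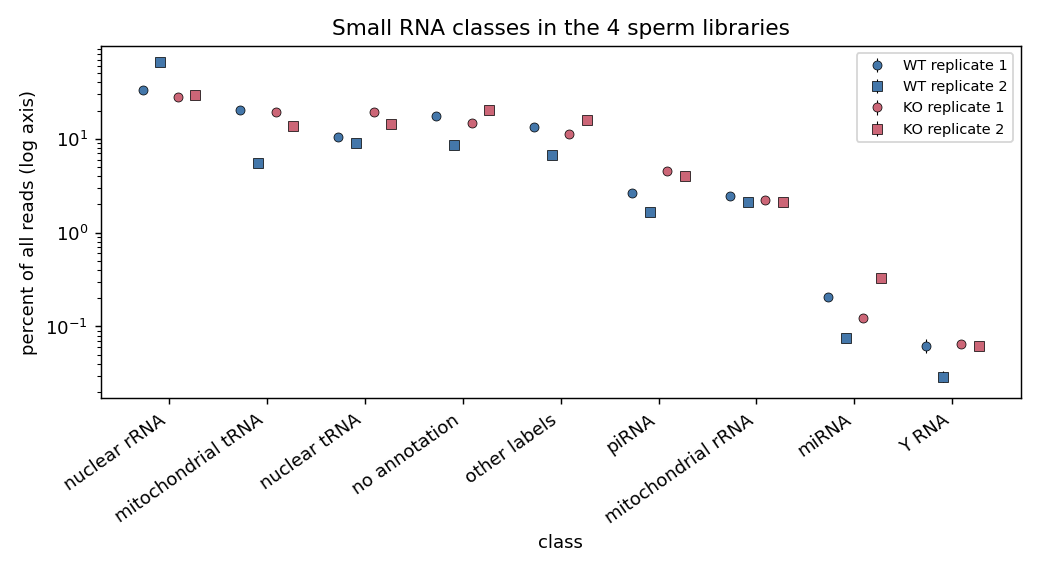
Share of all reads, in percent on a log axis, of each small RNA class in the 4 sperm libraries. Points are single libraries, with WT in blue, KO in red and the shape giving the replicate, and bars are Wilson 95% intervals of counting error, mostly smaller than the points. Nuclear rRNA reached 66.0% in WT replicate 2 and stayed between 28.1% and 32.8% in the other libraries.

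Single small RNA annotations did not pass the test between the sperm genotypes. The 28S rRNA annotation held 30.5% and 60.5% of the annotated reads in WT and 22.7% and 26.4% in KO (log2 fold change -1.62, SE 0.65, adjusted p = 0.808). Among tRNA fragments, those of mitochondrial tRNA-His-GTG had 0.02 (SE 0.65), tRNA-Glu-CTC 0.54 (SE 0.58), tRNA-Glu-TTC -1.18 (SE 0.71), tRNA-His-GTG -0.92 (SE 0.83) and mature tRNA-Lys-TTT -1.78 (SE 1). Among microRNAs, mir-3535 had 350 and 379 reads in WT and 775 and 2136 in KO (0.38, SE 0.79). The epididymal microRNA mir-10b had 22, 90, 24 and 132 reads (-0.80, SE 1.03), mir-30a had -0.44 (SE 1.10), mir-1843b 0.13 (SE 1.06) and mir-148a -0.23 (SE 1.04). Of 122 annotations tested, edgeR called 0 higher and 0 lower, as did DESeq2 and limma-voom, and 3 were higher and 2 lower at an unadjusted p under 0.05. Counting distinct sequences gave 15 higher and 3 lower of 2527. Without WT replicate 1 the 28S rRNA annotation had -1.89. Without WT replicate 2 the string naming snoRNA, DNA and mRNA, in that order, had -3.24. Each of these fits left 1 WT library. With all 4 libraries that string had -2.37, and its names in other orders had -0.58, -0.95, -0.22 and 1.63.

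The remaining annotations with the smallest p joined several kinds of entry. Each order of names was counted as its own annotation. The string naming other RNA, DNA and miRNA, in that order, had 0 reads in WT and 26 and 16 in KO. The same names in other orders had WT reads. DNA, miRNA and other RNA had 97 and 29 in WT and 96 and 659 in KO, and miRNA, DNA and other RNA had 6 and 8 against 109 and 51. With names sorted, 0 of 87 annotations were higher and 0 lower at an unadjusted p under 0.05 (edgeR). The string DNA, mRNA and other RNA had a log2 fold change of 3.35 (SE 1.12), and its names in other orders had 2.02 and 0.56. The string DNA, gene region, other, snRNA and mRNA had 2.96 (SE 1.10), and 2.19 in another order. The string rRNA, DNA and mRNA had 3.40 (SE 1.55), with 5 and 20 reads in WT and 527 and 12 in KO. Its names in other orders went the other way, at -1.38, -1.88, -1.39 and -1.26. The strings snRNA, DNA and scRNA, and snRNA and DNA, in those orders, had -3.03 (SE 1.20) and -1.80 (SE 0.85). The order scRNA, snRNA and DNA had a positive log2 fold change, with 8 and 19 reads in WT and 207 and 40 in KO. The order DNA, scRNA and snRNA had -0.15 (SE 0.89). The order DNA and snRNA had -0.61 (SE 0.69), with 1196 and 7270 reads in WT and 6055 and 5433 in KO. Of the 9 tested tRNA annotations in the list of abundant sperm tRNA parents, 0 were called and 5 were higher (median 0.22). Of the epididymal and mature-sperm microRNA families 3 were tested and 0 called (median -0.44). The spermatogenic microRNA families had 5, 0, 0 and 0 reads and the blood, muscle and liver markers 1, 1, 1 and 0. For none of the 4 lists was a member called adjusted over the list alone. In simulated data 0% of 4-fold and 75% of 16-fold changes in single annotations were recovered, and sizes between these were not tested.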

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

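The share of sperm reads that matched the genome, a column that no comparison above uses, was higher in both KO libraries than in both WT libraries. It was 69.6% and 70.8% in KO, against 63.3% and 34.4% in WT, and this share was not tested. The library with the lowest match, WT replicate 2, also had the highest nuclear rRNA share. That share was 32.8% and 66.0% in WT and 28.1% and 29.1% in KO. The genome match can therefore not be read as a difference apart from the nuclear rRNA share.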

How the results depend on the processing

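Settings that name the third WT oocyte library, library weights, sorted annotation names and library sizes without rRNA reads were chosen after seeing the data, and the cause of a change was not tested unless stated. Genes higher in the libraries labelled KO numbered 0 in the main test, 96 with DESeq2, 7 and 8 with limma on log2 TPM plus 1 and plus 0.1, and 2 with library weights. Without 1 library each they ranged from 0 to 81. Without the third WT library they numbered 415 with DESeq2, 5 with limma-voom, 31 with the replicate block (whose 37 calls in all share 30 with the 92 of edgeR), 81 with RLE factors and 65 with library totals. Genes lower numbered 2, against 25, 5 and 5, and 6 in the same order, ranged from 1 to 11 without 1 library, and numbered 71, 6, 6, 11 and 9 without the third WT library. Isca2 ranged from 0.15 to 2.48 without 1 library, and passed the threshold in DESeq2 without the third WT library (2.49). The common dispersion was 0.222 with 6 libraries and 0.103 without that one. Gene lists called numbered 3, with 1 without mitochondrially encoded genes, a setting that removes one of the lists itself, 0 with an estimated correlation or fry, and 6 with library weights. They ranged from 1 to 6 without 1 library. Without the third WT library they numbered 7 with limma-voom, 3 with the block (granulosa and antioxidant lists at 0.066 and the stress-response list at 0.0869), 6 with RLE factors, 5 with library totals and 0 with an estimated correlation. Without that library 3 of the genes followed here changed sign and passed. Fth1 moved from -3.31 to 1.56, its range over leaving out 1 library being -3.87 to 1.56 (DESeq2 1.55, RLE factors 1.56, library totals 1.55, not called in limma-voom, adjusted p 0.0791, or with the block, adjusted p 0.0502). Xbp1 moved from -0.32 to 7.95, with a range of -0.89 to 7.95 (8.26, block 7.85, 7.95, 7.94), and Skil from -0.59 to 4.55, with a range of -1.15 to 4.55 (4.56, block 4.76, 4.55, 4.53), while limma-voom without that library called neither (adjusted p 0.387 and 0.140). Of the other single genes and features under each setting, 1361 values kept their side of the threshold, 78 newly passed and 1 was lost. For list tests these numbers were 349, 21 and 25. The replicate block left the 6-library calls at 0 higher and 2 lower, and its sperm calls at 0 and 0. With the block 2 gene lists were called in the 6 libraries, and the mitoribosome list was lost (camera adjusted p 0.0559). Deviations of same-numbered oocyte libraries correlated at 0.06, -0.11 and 0.01, and no label ties a number to an animal. In sperm the correlation was -0.28. Sperm annotations higher numbered 0, against 15 counted by sequence and 1 without rRNA reads. Those lower numbered 0, against 3 by sequence, and ranged from 0 to 1 without 1 library, where the lone library of a group is assumed to vary like the other group. Library totals moved the median sperm log2 fold change from -0.09 to 0.44, which is more than many of the changes given. As shares of distinct sequences, the KO minus WT differences were -2.67 points for nuclear rRNA, -0.54 for nuclear tRNA and 0.12 for piRNA, against -20.8, 7.07 and 2.13 as shares of reads. Without 1 library each they ranged from -37.4 to -4.21, from 4.56 to 9.58 and from 1.63 to 2.63.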

Other observations

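The tests of explanations and the splits in this part were chosen after the results were seen. Several granulosa and cumulus genes varied widely among the oocyte libraries labelled KO, while Cyp19a1 (52.0 to 60.3 CPM) and Serpine2 (1116 to 1281 CPM) did not. The steroid dehydrogenase gene Hsd3b1 had 0, 49.4 and 39.7 CPM in replicates 1, 2 and 3, and the gap junction gene Gja1 had 37.7, 112 and 125 CPM, against 9.86, 0.39 and 0.10 CPM in WT. The inhibin gene Inha had 0.22, 4.37 and 36.5 CPM against 5.70, 0.15 and 0.28 CPM in WT, and the follistatin gene Fst 7.97, 30.3 and 24.9 CPM against 1.49, 0 and 1.38 CPM. The growth factor gene Igf1 rose without WT replicate 3 (log2 fold change 3.47, adjusted p = 0.0255, edgeR) and had 9.90 to 20.4 CPM in the libraries labelled KO. Hsd3b1, Gja1, Fst and Igf1 are not in the fixed granulosa list and were named after the data were seen. In that list, Foxl2 and Ptx3 reached at most 0.25 and 0.06 CPM in the libraries labelled KO. Without WT replicate 3, 10 of its 12 tested members were higher.

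The oocyte growth factor genes Gdf9 and Bmp15 held steady levels in all 6 libraries, at 2994 to 3910 CPM and 1817 to 2097 CPM. The zona pellucida gene Zp2 did not, with 602, 112 and 2135 CPM in WT and 132 to 197 CPM in the libraries labelled KO. The non-coding nuclear RNA Malat1 had 826 CPM in WT replicate 3 and 180 to 239 CPM in the libraries labelled KO, against 57.2 and 17.2 CPM in WT replicates 1 and 2. Lrmda had 8.67, 7.30 and 14.5 CPM in WT and 0, 0.34 and 0 CPM in the libraries labelled KO.

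The genes that rose in the libraries labelled KO without WT replicate 3 could come from granulosa or cumulus cell RNA carried into those libraries. The median of the granulosa list lay at percentile 100 of 10000 matched random lists, with 10 of 12 tested members higher, although 4 of its 24 members stood at 10 CPM or more in WT replicates 1 and 2. Inha at 0.22 CPM in KO replicate 1, where Nupr1 had 139 CPM, shows that Nupr1 did not follow this marker in every library. Depth is argued against for the 92 calls, since all of them remained after each library was thinned to 17792138 counts. The set was not stable, as the thinned counts gave 115 higher and 11 lower. An effect of the genotype itself, or another state of the oocytes, stays open and was not tested.

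The third WT oocyte library stood apart, and RNA from blood or immune cells is a candidate source. The immune list lay at percentile 100 of the matched lists, only 1 of its 18 members stood at 10 CPM or more in WT replicates 1 and 2, and Adgre1, Lyz2, Ccl6 and Il1rn reached 289, 125, 1433 and 1051 CPM. Such cells bring no oocyte transcripts, yet the oocyte list also lay at percentile 100 there (median 1.21-fold, 8 of 29 genes over 2-fold, Khdc3 5.69-fold), which argues against them as the source of that part. Some of these oocyte genes also differed between WT replicates 1 and 2, so this part is not confined to WT replicate 3. Zp2 had 602 and 112 CPM there, Nlrp5 927 and 486 CPM and Khdc3 34.9 and 20.4 CPM, while Gdf9 differed little (3288 and 3014 CPM). Gm15446 at 164 CPM in WT replicate 3 argues against an exchange with a library labelled KO. Less mature oocytes or another donor may account for the oocyte genes, which was not tested.

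DNA around the targeted gene could differ between the genotypes, since a targeted allele can carry flanking DNA of another strain. Of the 92 genes called without WT replicate 3, 85 had a position on a nuclear chromosome and 1 lay on chromosome 12 (Ifi27, 18.7 Mb from Isca2), and 6 of the lower genes lay on 5 nuclear chromosomes, which argues against this for the placed genes as a set. Another 4 lower genes, Gm47180 among them, had no position. For Nlrp4g, the other Nlrp4 genes together gained 495 CPM (4325 ± 769 to 4820 ± 321 CPM) while it lost 279 CPM, so a shift of reads between relatives and a true loss cannot be told apart at this spread. Strain or donor variants elsewhere in the genome stay open and were not tested.

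The 6 oocyte libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes, the highest other split called 1, and 1 of the 10, the real one, reached the real number. For gene lists the real split called 3, the highest other 7, and 7 of the 10, the real one included, reached the real number. The split with 7 lists set WT replicate 3 and KO replicates 2 and 3 against the others, which points to a structure of the libraries beside the genotype.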
